A study of Mus musculus with 6 samples.

How the data were processed

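RNA from sorted mouse bone marrow B cells was measured on 6 Affymetrix arrays with 45101 probe sets. The deposited values are probe set signals, that is, array intensities on a linear scale. They were made with MAS5, per the submitters' processing notes; its version and the scanner settings are not given in the sources used here. The deposited intensities of every array have a mean of 500.0 once the lowest and highest 2% of probe sets are left out, so each array carries a single scaling factor and its distribution was not matched to that of other arrays. Such scaling turns a weak array into one with raised background, and every level below should be read with the control signals given at the start of the results. No detection calls were used, and the number of arrays limits the precision.

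The arrays fall into 3 groups of 2 by their titles: TAK1-deficient Igκ+, wild-type Igκ+ and wild-type Igλ+. The array whose title carries the suffix "-rep" is called replicate 2. The labels do not say whether replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. No array column was without a sample.

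Probe sets were named from the platform's annotation table. Of the probe sets, 34945 carried 1 gene symbol, 932 carried several, 9160 had no listed gene and 64 were Affymetrix controls. The Entrez identifiers of 34741 single-gene probe sets were found in a RefSeq table of assembly GRCm38.p6, used for names only, and 0 symbols needed updating. Probe sets with several genes entered no gene test and are given only as a class for the light chain loci. No genome build is named with the arrays, so no coordinates are given.

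Signals were converted to log2(signal + 16). A fold change on this scale understates the change of dim genes. The probe set with the highest mean over the 6 arrays stood for each gene, and genes with a mean above the 40th percentile of all probe sets were kept, which left 11694 of 18193 genes. Groups were compared with limma (version 3.58.1, R 4.3.3): lmFit with a mean per group over all 6 arrays and 3 residual degrees of freedom, eBayes with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists were compared with all other genes by limma's camera test with a preset correlation of 0.01, adjusted over the 32 lists with at least 5 measured members. The 33 lists, 8 of them markers of other cell types, were fixed before the data were examined, as were the tests and the rule for named genes. As a description without a p-value, genes were counted whose log2 difference was at least 1 in the same direction in all 4 array pairs of a comparison. The same count was made for the 2 regroupings that mix the groups. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

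Genes were named by a fixed rule. In each comparison and direction, the 12 largest log2 changes were taken among genes past the threshold whose groups did not overlap, with at most 3 immunoglobulin variable-region genes. A direction with fewer than 5 was filled to 5 by the smallest unadjusted p, and those genes are given as values only. Map3k7, the light chain loci and up to 4 examples per list were always taken.

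The code was tested on simulated data with 200 changed genes among 11694. For TAK1-deficient against wild-type Igκ+ cells it recovered 28%, 90%, 100% and 100% of genes changed by 1, 2, 3 and 4 log2 units, with 8 false calls. For wild-type Igλ+ against Igκ+ cells the shares were 36%, 90%, 100% and 100%, with 14 false calls. For TAK1-deficient Igκ+ against wild-type Igλ+ cells they were 36%, 86%, 100% and 100%, with 9 false calls. Of 50 random lists of 25 genes, 0 were called in each comparison. The simulated noise was independent between genes, so this count does not cover lists whose members vary together. Granulocyte markers, for example, had an estimated correlation of 0.928. Nor do the recovery shares cover genes that differ strongly between replicates. In the deposited data Igkv14-111, with a log2 difference of -5.51 between the wild-type groups, did not pass.

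The alternatives fixed in advance were pseudocounts of 1 and 64, no filter, a filter at the 60th percentile, quantile normalization, median centring, every probe set as its own feature, eBayes without a trend, only the 4 arrays compared, the title suffix as a block, an estimated correlation in camera, and leaving out each array in turn. After the data were seen, 3 more were added: 1 control array for each change in the correlation of changes, scaling on the spiked hybridization controls, and a lowess adjustment (span 0.2) of each TAK1-deficient array for its trend against the mean wild-type level of a probe set, called the level adjustment below.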

Results

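The arrays measured RNA of bone marrow B cells from C57BL/6 mice aged 8 to 12 weeks. Cells bearing CD3, Ter119, CD11b, DX5 or Gr1 had been depleted, and the remaining B cells were sorted by the light chain on their surface, Igκ or Igλ. TAK1, encoded by Map3k7, is a kinase that links receptors to NF-κB and MAP kinases. The 3 groups were TAK1-deficient Igκ+, wild-type Igκ+ and wild-type Igλ+ cells, with 2 arrays each. The genotype labels read mb-1/TAK1f/f for the first and mb-1/TAK1+/+ for the others, while the series title names TAK1-/- cells. The labels do not say what mb-1 stands for or how far TAK1 was lost, so "TAK1-deficient" and "wild-type" are used here as names of these groups. The design allows a comparison of genotypes at the same light chain, a comparison of light chains at the same genotype, and another in which genotype and light chain differ together.

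Transcripts of B cell genes were measured in every group. Cd79b, which encodes a signalling chain of the B cell receptor, had a signal of 15981 ± 675 (SD, n = 2) in TAK1-deficient Igκ+, 10313 ± 800 in wild-type Igκ+ and 10348 ± 423 in wild-type Igλ+ cells, and Ms4a1, which encodes CD20, had 24175 ± 3387, 10276 ± 268 and 10814 ± 739. Cd79a, the gene of the partner chain of Cd79b, went the other way, with 2880 ± 404, 7428 ± 1078 and 7164 ± 269. These genes were chosen after their values were seen. The higher Cd79b and Ms4a1 signals on the TAK1-deficient arrays are as deposited and are not given for other scalings. The highest signal of any probe set was 15310 to 16295 on the wild-type arrays, and 177337 and 167881 on the TAK1-deficient arrays. Whether signals this bright can be compared between the groups was not tested. The TAK1-deficient arrays differed from the other 4 in their control signals. The spiked hybridization controls, added in fixed amounts, had a geometric mean signal, averaged over the 2 arrays, of 50810 ± 4105 on the TAK1-deficient arrays, 4625 ± 8.47 on the wild-type Igκ+ arrays and 5255 ± 60.5 on the wild-type Igλ+ arrays. The median of all probe sets was 324 ± 0.942, 49.4 ± 6.38 and 56.4 ± 3.87, and the ratio of 3′ to 5′ Actb signal was 5.23 ± 1.49, 1.48 ± 0.0185 and 1.41 ± 0.236. Across probe sets, Pearson's r of log2 signals was 0.920 between the TAK1-deficient arrays, 0.962 to 0.984 among the wild-type arrays and 0.435 to 0.512 between a TAK1-deficient and a wild-type array. Probe sets are not independent replicates.

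**Figure D1:**
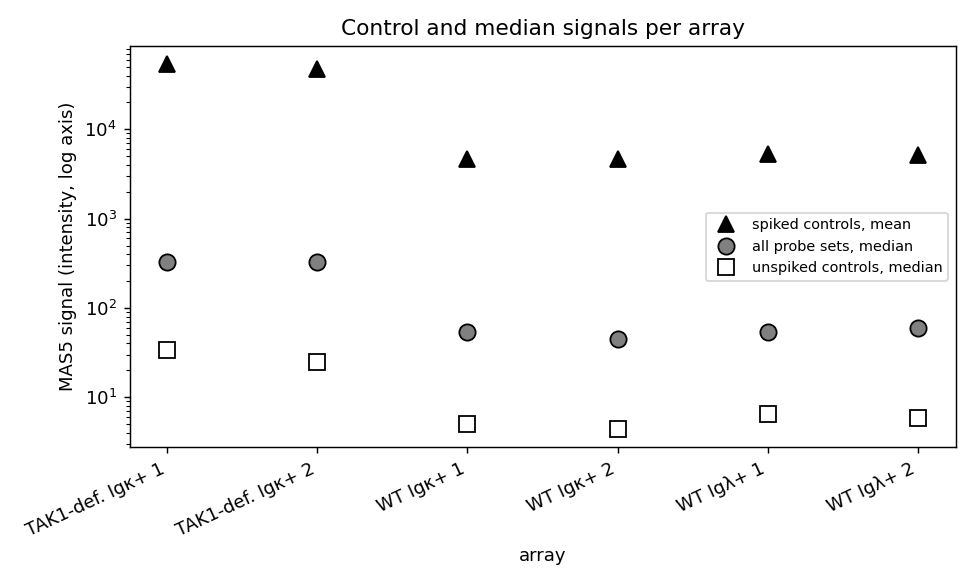
MAS5 signal (intensity, log axis) of the spiked controls (geometric mean), all probe sets (median) and unspiked controls (median) on each of the 6 arrays, a symbol per array and class. All 3 classes are higher on the TAK1-deficient arrays, where the spiked controls have a mean signal of 50810 against 4625 on the wild-type Igκ+ arrays.

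The first comparison asked what TAK1 deficiency changes in Igκ+ cells. Map3k7, the targeted gene, had a signal of 473 ± 179 (SD, n = 2) in TAK1-deficient and 2001 ± 276 in wild-type Igκ+ cells and fell by 2.09 ± 0.27 (SE) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.000184). In wild-type Igλ+ cells its signal was 2053 ± 135. Genes of similar wild-type level fell as well, with a median log2 change of -1.53, and Map3k7 stood at percentile 22.8 among 500 of them. Of its other 5 probe sets, those with wild-type Igκ+ means of 1053 and 1794 had log2 changes of -2.33 and -2.23 (percentiles 12.4 and 16.2 among genes of their level), and the remaining 3, at 377, 102 and 81.7, had -0.81, -0.99 and 0.30 (percentiles 33, 1.4 and 14). Where these probes lie relative to the deleted part of the gene is not known, so the signal is no check of the deletion, and with the level adjustment, chosen after seeing the data, the change was -0.62 (limma, Benjamini-Hochberg adjusted p = 0.0816).

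NF-κB target genes fell in TAK1-deficient Igκ+ cells. Of 33 measured, 26 fell and 2 rose, with a median log2 change of -1.55, and 28 passed when adjusted over the list alone. Ltb, which encodes lymphotoxin β, fell from 4145 to 305 (log2 change -3.70 ± 0.20 SE), the chemokine receptor genes Ccr7 and Cxcr5 fell from 4332 to 372 and from 3028 to 216, and Traf2, an adaptor of TNF receptors, fell from 545 to 57.1. Of the components of the NF-κB pathway 16 of 21 fell and 1 rose (18 passed adjusted over the list alone), among them Bcl10 (4756 to 731), Tnfaip3 (1750 to 281), the NF-κB subunit gene Rela (1648 to 192) and the NF-κB-inducing kinase gene Map3k14 (554 to 40.4). Genes of mature follicular B cells had a median log2 change of -1.81, with 19 of 23 that fell and 2 that rose (21 passed adjusted over the list alone). Among them were Ciita, the master regulator of MHC class II genes (1854 to 69.7), and Ccr6 (2525 to 397). The TAK1-deficient means of Traf2, Map3k14 and Ciita were below the 95th percentile of the unspiked controls there, 77.7 and 75.7. The sizes of their changes depend on the background. Of 30 genes of B cell receptor signalling 23 fell and 3 rose, with a median of -1.35 (27 passed adjusted over the list alone). Grb2 fell from 5768 to 1006 and Cd81 from 5665 to 834. These lists share members, so they are not separate results. Tnfaip3 is on both NF-κB lists, Bcl10 is also on the receptor signalling list, and Ccr7 and Cxcr5 are also follicular genes. In limma's camera test the Benjamini-Hochberg adjusted p was 0.0179 for NF-κB targets, 0.0471 for pathway components, 0.0281 for follicular genes and 0.0334 for receptor signalling. It was 0.609 for all 4 with an estimated correlation, and 0.215, 0.503, 0.401 and 0.846 with the level adjustment, which gave medians of -0.41, -0.28, -0.54 and -0.14. With that adjustment 11 NF-κB targets fell and 3 rose, 5 components fell and 3 rose, 9 follicular genes fell and 5 rose, and 5 receptor signalling genes fell while 9 rose. Of 18 alternatives, 15, 8, 14 and 14 kept the call of these lists. For pathway components it was lost (limma's camera test, Benjamini-Hochberg) without TAK1-deficient replicate 1 (adjusted p = 0.0550) and without wild-type Igκ+ replicate 2 (0.0511), with a pseudocount of 1 (0.0506), median centring (0.0518), the title suffix as a block (0.0548), spike-in scaling (0.0596), quantile normalization (0.139) and the stricter filter (0.388). With the stricter filter the adjusted p was 0.213 for NF-κB targets, 0.236 for follicular genes and 0.388 for receptor signalling (camera, Benjamini-Hochberg). After quantile normalization follicular genes (0.136) and receptor signalling (0.225, median -0.93) lost their call as well (camera, Benjamini-Hochberg). With median centring the 4 medians were -3.93, -3.90, -4.19 and -3.73. The median over all genes was -0.70 as deposited and -3.08 with median centring. Bright genes fell in general: as deposited, the 10% of probe sets with the highest wild-type level had a median of -1.46.

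Of the 8 lists of markers of other cell types, those of stromal and endothelial cells and of T cells passed the list test in this comparison. Of 12 stromal and endothelial and 17 T cell markers listed, 6 and 8 passed the filter on the mean over all 6 arrays. Markers dim on the wild-type arrays passed it only with a high signal on the TAK1-deficient arrays. The rise of such markers is therefore in part fixed by the filter. Of the 6 measured stromal and endothelial markers 5 rose, with a median log2 change of 3.96 (5 adjusted over the list alone). The matrix genes Dcn and Col1a2 rose from 15.8 to 1229 and from 22.0 to 1213. Of 8 T cell markers 6 rose and 1 fell, with a median of 2.64 (7 adjusted over the list alone); it was 0.26 with median centring and turned to -0.29 when the arrays were scaled on the spiked controls. The stromal and endothelial median was 1.58 and 0.74 with these scalings. Bcl11b, a transcription factor gene of T cells, rose from 10.5 to 2372, Icos from 16.6 to 1092 and Cd8a from 23.9 to 448. In limma's camera test the Benjamini-Hochberg adjusted p was 0.0179 and 0.0384, then 0.609 for both with an estimated correlation and 0.360 and 0.846 with the level adjustment, where 2 stromal and endothelial markers rose and 0 fell (median 1.84) and 2 T cell markers rose and 2 fell (median 0.49). Of 17 alternatives, 15 kept the call of the stromal and endothelial list and 13 that of the T cell list, which was also lost with a pseudocount of 1 (camera, Benjamini-Hochberg adjusted p = 0.0506) and after quantile normalization (0.156, median 1.07). The unspiked controls were brighter on these arrays as well (29.3 against 4.70). Of the 14 granulocyte and 14 monocyte markers, 10 each had higher values, with medians of 1.65 and 1.53 (0.32 and 0.35 with the level adjustment). Past the threshold 1 and 4 rose and 1 and 3 fell. Neither list passed (camera, Benjamini-Hochberg adjusted p = 0.199 and 0.170).

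The genes with the largest increases were 4933438K21Rik (log2 change 9.45 ± 0.48 SE), Gm3715 (9.36), Orly (9.02), Mup10 (8.93), a major urinary protein gene, 1700040G22Rik (8.26), Speer4cos (8.06), Vldlr (7.78), 9530057J20Rik (7.77), Ptn (7.71), Zfp462 (7.71), Ccdc30 (7.65) and Ccn1 (7.60). Their signals were 3683 to 24352 on average in TAK1-deficient and at most 33.6 in wild-type Igκ+ cells, and in 11 of the 12 genes at least 1 wild-type Igκ+ array was at the level of unspiked controls. The largest decreases were those of Rassf2 (-5.73 ± 0.31 SE, from 1783 to 17.7), Rab30 (-5.20), 0610012G03Rik (-5.17), Igha (-5.15), which encodes the IgA heavy chain constant region, Zfp395 (-5.08), Fastk (-4.82), H2-DMa (-4.66), a gene of MHC class II peptide loading, Spg21 (-4.66), Arap1 (-4.54), Slc25a22 (-4.46), Ciita (-4.44) and Pwp1 (-4.42). Rassf2, 0610012G03Rik, Ciita and Pwp1 each had 1 further probe set without a decrease. Of the 12 genes with decreases, 10 were at the level of unspiked controls on at least 1 TAK1-deficient array and 8 on both. A signal counts as at that level here when it is no higher than the 95th percentile of the unspiked controls of its array, 77.7 and 75.7 on the TAK1-deficient and 10.3 to 17.4 on the wild-type arrays. The sizes and order of both sets of changes depend on the background. The 12 genes with increases were dim on all 4 wild-type arrays, so they passed the filter only through the TAK1-deficient arrays. The control probe set of the B1 repeat had 49589 and 45652 on the TAK1-deficient arrays, against 2350 to 3341 on the wild-type arrays. That of the B2 repeat had 121919 and 99640, against 8748 to 9590. Whether signal of this kind adds to the named increases was not tested. The rule took these 24 genes from those past the threshold as deposited (limma, Benjamini-Hochberg adjusted p from 3.94e-06 to 0.00317). As the largest of the changes called, all 24 also passed with the level adjustment (limma, Benjamini-Hochberg adjusted p from 6.27e-05 to 0.0285).

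At light chain probe sets of 1 gene, TAK1-deficient Igκ+ cells had a median log2 difference of -2.29 for κ (14 of 16 lower) and -2.53 for λ (3 of 3 lower). In limma, 3 of the 16 κ and 3 of the 3 λ probe sets had an unadjusted p under 0.05. All 3 λ probe sets are of Iglv1, so they are repeat readings of that gene. Some of the 16 κ probe sets share a gene too. The higher κ probe sets were bright ones, of Igk at 356% and 350.2% and of Igkv8-30 at 439% and 391% of the wild-type Igκ+ mean. These values are as deposited. With median centring and with spike-in scaling 16 of 16 κ probe sets were lower. The κ and λ medians were -4.67 and -4.91 with median centring, -5.12 and -5.71 with spike-in scaling and -1.50 and -1.38 with the level adjustment. The 6 κ probe sets of several genes had a median of 1.53, which turned to -0.18 after quantile normalization, -0.85 with median centring and -1.80 with spike-in scaling. In total 8876 of 11694 genes passed (limma, Benjamini-Hochberg): 3052 rose and 5824 fell. The groups did not overlap for 89.6% of genes, against 33.3% by chance. At least 2-fold apart in all 4 array pairs were 6444 genes, against 2 and 4 in the regroupings that mix the genotypes. The changes followed the wild-type level: the 10% of probe sets with the lowest wild-type level had a median log2 change of 3.10 and the 10% with the highest level one of -1.46. Of the 7761 further probe sets of called genes, 41.5% had a change opposite in sign to the call. With the level adjustment 4809 genes passed, 2639 higher and 2170 lower, of which 3371 had the same call as before. The median log2 change of all genes was -0.70 as deposited, -0.91 after quantile normalization, -3.08 with median centring, -3.73 with spike-in scaling and -0.02 with the level adjustment, and the share of higher genes among those called was 34.4%, 30.4%, 12.9%, 7.19% and 54.9%.

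**Figure D2:**
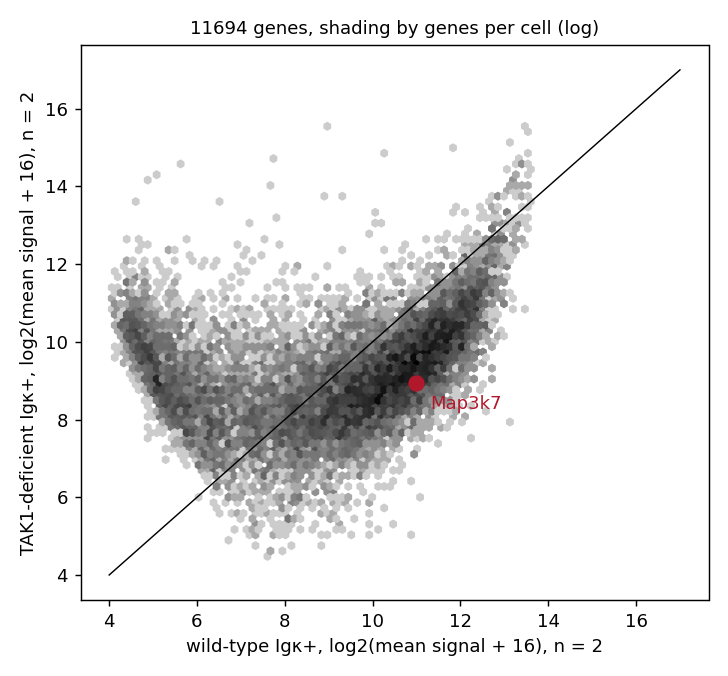
Mean signal of 11694 genes in wild-type Igκ+ (horizontal) and TAK1-deficient Igκ+ cells (vertical), both as log2(mean signal + 16) with n = 2 arrays; shading gives the number of genes on a log scale and the line marks equal signals. Most dim genes lie above the line and most bright genes below it, and Map3k7 (2001 against 473) lies below it.

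The second comparison asked how wild-type Igλ+ cells differ from Igκ+ cells. Immunoglobulin κ transcripts were lower in both Igλ+ samples, by very different amounts. Over the 16 κ probe sets of 1 gene with a wild-type Igκ+ mean of at least 200, the median signal was 0.405% of that mean on Igλ+ replicate 1 (range 0.0735 to 4.16%) and 26.5% on replicate 2 (9.74 to 83.9%). Igkv15-103 had 3963 ± 688 (SD, n = 2) in Igκ+ and 201 ± 262 in Igλ+ cells, and Igkv14-111 had 6604 ± 875 and 433 ± 601, at the level of unspiked controls on Igλ+ replicate 1. The 3 λ probe sets of 1 gene, all of Iglv1, had medians of 174% and 204% of the Igκ+ mean on Igλ+ replicates 1 and 2, and 1 of the 3 was lower on average, at 56.7% and 103%. Their median log2 difference was 0.97, and it was 1.21 and 0.54 without Igκ+ replicates 1 and 2. In limma's test 0 genes passed after Benjamini-Hochberg adjustment (smallest adjusted p = 0.99998), while 239 had an unadjusted p under 0.05. Among these light chain probe sets of 1 gene, 14 of 16 κ and 2 of 3 λ had an unadjusted p under 0.05 in limma.

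Without Igλ+ replicate 2, 68 genes passed (limma, Benjamini-Hochberg), of which 48 were higher and 20 lower in Igλ+ cells, and 12 of the lower were κ genes. All 48 higher genes had their highest wild-type signal on Igλ+ replicate 1. Of these, 8 were on the lists of granulocyte (Ltf, Lcn2, Fcnb), monocyte (Fcgr3, Vcam1, Ccr2), erythroid (Car1) and megakaryocyte or basophil (Ppbp) markers, genes named after their values were seen. Without Igλ+ replicate 1, 7 genes passed, all lower: 4 κ genes, Igha, Jchain, which encodes the joining chain of polymeric IgA and IgM, and Pclaf. Pclaf lies outside the rule for named genes and was chosen after its values were seen. A lone remaining array is assumed to vary like the other groups. The 2 groups did not overlap for 22.7% of genes, against 33.3% by chance, and 19 genes were at least 2-fold apart in all 4 array pairs, against 104 and 23 in the mixed regroupings.

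**Figure D3:**
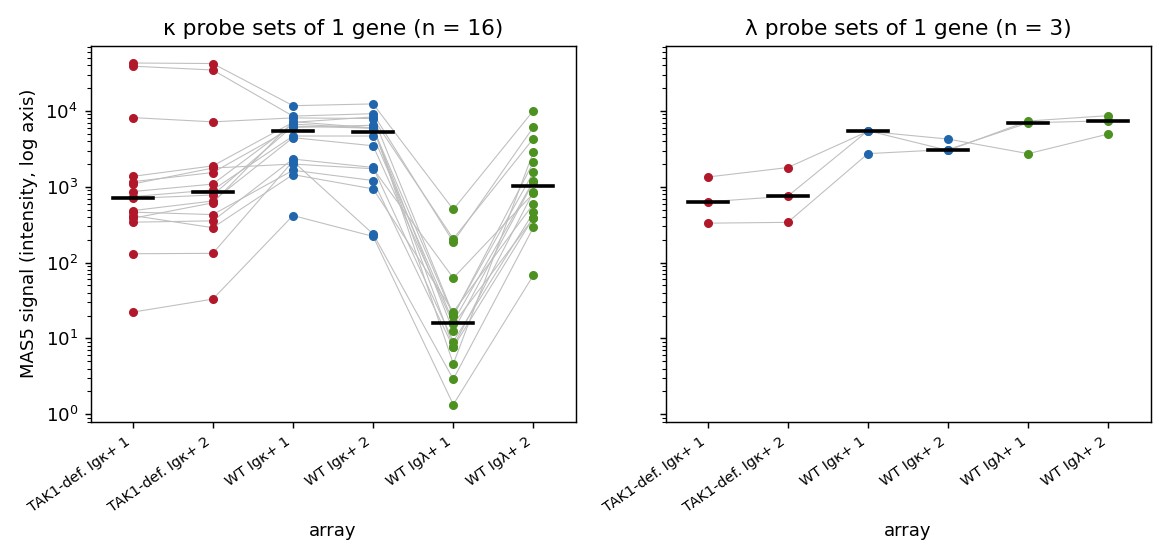
MAS5 signal (log axis) of κ (left, 16) and λ (right, 3) probe sets of a single gene on each of the 6 arrays; points are probe sets, grey lines join a probe set across arrays, and black bars are medians. On Igλ+ replicate 1 κ signals have a median of 0.405% of the wild-type Igκ+ mean, and on replicate 2 of 26.5%. The 3 λ probe sets are all of Iglv1.

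Of genes of pro-B and pre-B cells, 13 of 17 had higher values in Igλ+ cells, with a median log2 difference of 0.24, and 0 passed the threshold (limma's camera test, Benjamini-Hochberg adjusted p = 0.0683). By array the median stood at -0.04 and 0.35 on Igλ+ replicates 1 and 2 and at 0.12 and -0.22 on Igκ+ replicates 1 and 2, relative to the mean of these arrays. Rag1, which encodes part of the V(D)J recombinase, had 397 ± 115 (SD, n = 2) against 124 ± 77.1 in Igκ+ cells, a log2 difference of 1.65 ± 0.45 (SE). Rag2 had 40.4 ± 1.75 against 15.2 ± 12.2, where Igκ+ replicate 2 was at the level of unspiked controls, Igll1, a surrogate light chain gene, had 3285 ± 142 against 2057 ± 1168, and Il7r, the interleukin 7 receptor gene, 697 ± 118 against 345 ± 292. Lef1, a transcription factor gene of the same list chosen after its values were seen, was lower, with a log2 difference of -1.01, and was called without Igλ+ replicate 2 (-1.82; limma, Benjamini-Hochberg adjusted p = 0.0186). Genes of V(D)J recombination showed no common direction, with 13 of 23 higher, 10 lower and a median of 0.02 (camera, Benjamini-Hochberg adjusted p = 0.613), where the test pointed down.

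The genes with the smallest unadjusted p in the higher direction were Slc1a4, an amino acid transporter gene (325 ± 27.4 in Igλ+ against 97.6 ± 8.77 in Igκ+ cells), F5 (215 ± 50.96 against 37.5 ± 8.61), Mcf2l (320 ± 113 against 65.8 ± 23.3), Dapl1 (55.8 ± 15.2 against 6.22 ± 4.23, at the level of unspiked controls on both Igκ+ arrays) and Wfdc21 (976 ± 333 against 374 ± 13.9). In the lower direction, besides the κ genes, they were Tfdp1, which encodes a partner of E2F factors (1013 ± 47.4 against 1927 ± 69.2), Uhrf1 (1636 ± 349 against 2962 ± 221) and Arhgap26 (621 ± 64.8 against 1145 ± 73.5), of whose 4 probe sets 2 had a difference of the same sign. On the TAK1-deficient arrays Slc1a4, F5, Mcf2l, Dapl1 and Wfdc21 had 904, 537, 343, 1201 and 627, and Tfdp1, Uhrf1 and Arhgap26 had 1598, 1578 and 1014. Dim genes were higher on these arrays in general.

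Of 32 gene lists, 9 passed limma's camera test with Benjamini-Hochberg adjustment, and each lost its call with an estimated correlation (adjusted p = 0.663). No single member of any list passed over all genes, and adjusted over the list alone 1 dendritic cell marker, Cox6a2, passed. Interferon-stimulated genes were higher in Igλ+ cells on average, with 29 of 32 above the Igκ+ mean and a median log2 difference of 0.32 (adjusted p = 0.000429), for example Mx1 (1524 against 1023) and Oas1a (840 against 425). Proliferation genes were lower, with 30 of 35 below and a median of -0.44 (adjusted p = 1.5e-06), for example Top2a (694 against 1608) and Mki67 (791 against 1610). Plasma cell genes were lower by their mean of -0.47, with a median of -0.06 (adjusted p = 0.00202); Jchain had 2132 against 6984 and Sdc1, the CD138 gene, 1272 against 2094. Survival and apoptosis regulators, 9 higher and 11 lower, had a median of -0.14 (adjusted p = 0.0288), and lost the call with the stricter filter and after quantile normalization (adjusted p = 0.117 and 0.160). Markers of granulocytes (median 1.47, adjusted p = 0.00948), dendritic cells (0.49, 0.00477), erythroid cells (0.91, 0.0162) and megakaryocytes or basophils (1.40, 0.0427) were higher and those of NK cells lower (-0.77, 0.0198). The megakaryocyte or basophil list lost its call with a pseudocount of 1 (adjusted p = 0.158) and after quantile normalization (0.160, median 0.79), the erythroid list after quantile normalization (0.0519, median 0.56), all in camera with Benjamini-Hochberg adjustment. The NK list lost it with median centring (0.117) and spike-in scaling (0.202). The granulocyte and plasma cell lists lost it with the stricter filter (0.0971 and 0.0768).

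Each of these 9 lists lost its call or changed direction when some single array was left out. Relative to the mean of the 4 wild-type arrays, the median granulocyte marker stood at 3.92 on Igλ+ replicate 1, -2.39 on Igλ+ replicate 2, 0.45 on Igκ+ replicate 1 and -2.11 on Igκ+ replicate 2. The signal of S100a8, a granulocyte gene chosen after its values were seen, was 8309, 56.8, 1189 and 65.9 on these arrays. Proliferation genes stood at 0.45, -0.77, 0.87 and -0.36, and interferon-stimulated genes at 0.34, -0.08, -0.04 and -0.30, so that Igλ+ replicate 2 lay below Igκ+ replicate 1. Without Igλ+ replicate 1 the medians of the granulocyte, erythroid and megakaryocyte or basophil lists turned to -1.58, -0.24 and -1.22, and the adjusted p of the interferon-stimulated, dendritic cell, plasma cell and survival lists became 0.399, 0.356, 0.0739 and 0.653 (limma's camera test, Benjamini-Hochberg). The median of interferon-stimulated genes was 0.05 without Igλ+ replicate 1 and 0.54 without replicate 2, that of dendritic cell markers 0.11 and 0.97. The survival median was -0.03 without Igκ+ replicate 2 and -0.26 without Igλ+ replicate 2, and the plasma cell median -0.22 without Igκ+ replicate 2 and -0.01 without Igλ+ replicate 1. Without Igλ+ replicate 2 the medians of the proliferation and NK lists turned to 0.22 and 0.41, and without Igκ+ replicate 2 that of the NK list to 0.60, with the survival, granulocyte and megakaryocyte or basophil lists at an adjusted p of 0.330, 0.558 and 0.560. Without Igκ+ replicate 1 the proliferation median turned to 0.14 (adjusted p = 0.820) and the plasma and erythroid lists had an adjusted p of 0.157.

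**Figure D4:**
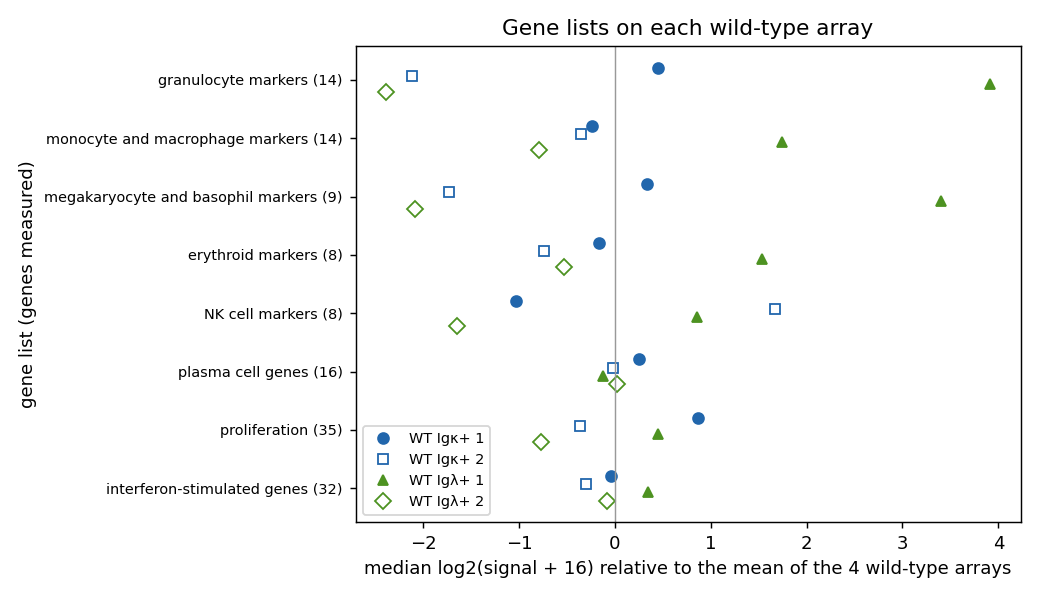
Median log2(signal + 16) of 8 gene lists on each of the 4 wild-type arrays, relative to the mean of these arrays; symbols are arrays, filled for replicate 1 and open for replicate 2, and the number of genes measured is in parentheses. Granulocyte markers stand at 3.92 on Igλ+ replicate 1 and at -2.39 on replicate 2.

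The last comparison set TAK1-deficient Igκ+ against wild-type Igλ+ cells, which differ in genotype and light chain. The κ probe sets of 1 gene had a median log2 difference of 2.30 and the λ probe sets of 1 gene one of -3.51; the κ median turned to -0.68 when the arrays were scaled on the spiked controls and to -0.32 without Igλ+ replicate 1, and was 0.07 with median centring and 4.40 without Igλ+ replicate 2. The λ median was -5.74 with median centring and -6.50 with spike-in scaling. NF-κB target genes fell, with 24 of 33 lower and 2 higher past the threshold (26 adjusted over the list alone) and a median of -1.59, for example Ltb (4039 to 305). Genes of the unfolded protein response fell in 17 of 20 cases and rose in 1 (18 adjusted over the list alone), with a median of -1.52, for example the protein disulphide isomerase gene Pdia3 (3386 to 339) and Herpud1 (3356 to 489). Follicular genes (20 of 23 fell, 2 rose, 22 adjusted over the list alone), receptor signalling genes (24 of 30 fell, 4 rose, 28 adjusted over the list alone) and NF-κB components (16 of 21 fell, 2 rose, 18 adjusted over the list alone) were lower, and 5 of 6 stromal and endothelial markers rose (5 adjusted over the list alone), with Dcn from 18.3 to 1229. In limma's camera test the Benjamini-Hochberg adjusted p of these 6 lists was 0.0313 to 0.0391, and it was 0.647 for each with an estimated correlation and 0.269 to 0.993 with the level adjustment. The level-adjusted medians were -0.44 for NF-κB targets, -0.36 for the unfolded protein response, -0.42 for follicular genes, -0.09 for receptor signalling, -0.38 for NF-κB components and 1.53 for stromal and endothelial markers. With median centring they were -3.82, -3.76, -4.10, -3.54, -3.82 and 1.46. The median over all genes was -0.71 as deposited and -2.94 with median centring. With the level adjustment 11 NF-κB targets fell and 3 rose, 7 genes of the unfolded protein response fell and 1 rose, 8 follicular genes fell and 5 rose, 8 receptor signalling genes fell and 8 rose, 6 NF-κB components fell and 3 rose, and 1 stromal and endothelial marker rose. Of 18 alternatives, 14 kept the call of the NF-κB target, follicular and receptor signalling lists and 12 that of the unfolded protein response and NF-κB component lists, and of 17 alternatives 15 kept that of stromal and endothelial markers. In the same test the adjusted p after quantile normalization was 0.0579 for NF-κB targets, 0.117 for follicular genes, 0.246 for receptor signalling, 0.130 for NF-κB components and 0.174 for the unfolded protein response (limma, Benjamini-Hochberg). With the stricter filter it was 0.220 to 0.384 for these 5 lists. Median centring and spike-in scaling also cost the call of the unfolded protein response (0.0861 and 0.0829) and of NF-κB components (0.0567 and 0.0539). As in the first comparison, the NF-κB, follicular and receptor signalling lists share members. The filter in part fixes the rise of the stromal and endothelial markers here too.

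In this comparison 8920 of 11694 genes passed (limma, Benjamini-Hochberg), 3017 higher and 5903 lower, and 4877 with the level adjustment, 2564 higher and 2313 lower. The largest increases were those of Orly (8.79), 4933438K21Rik (8.76), 1700040G22Rik (8.50), Mup10 (8.37), Gm3715 (8.16), Speer4cos (8.09), the homeobox gene Hoxc8 (7.48), Vldlr (7.47), Fign (7.37), Zfp462 (7.36), Dmp1 (7.35) and 3110009F21Rik (7.28), and the largest decreases those of Rassf2 (-5.31), 0610012G03Rik (-5.08), Rab30 (-4.94), Arap1 (-4.92), Fastk (-4.85), Zfp395 (-4.84), Slc25a22 (-4.80), Spg21 (-4.63), Dpcd (-4.59), Arv1 (-4.45), H2-DMa (-4.45) and Rnaseh2c (-4.42), all as log2 changes. Of the 12 increases 10 had at least 1 wild-type Igλ+ array at the level of unspiked controls, and of the 12 decreases 10 had both TAK1-deficient arrays there, so their sizes and order depend on the background. The genes with increases again passed the filter only through the TAK1-deficient arrays. Map3k7 fell by 2.13 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.000170), and with the level adjustment its change was -0.66 (limma, Benjamini-Hochberg adjusted p = 0.0659). The changes of TAK1-deficient Igκ+ and wild-type Igλ+ cells against wild-type Igκ+ cells had r = 0.306 across genes (Spearman's rho 0.272), which are not independent replicates. Simulated unchanged groups with shared simulated controls gave r = 0.498 and a covariance of 0.0630. Independent noise and equal group sizes set such an r in advance. The observed covariance was 0.256, a difference of 0.193. The simulation covers only the share that independent noise in shared controls gives, so this difference is no test of a common change. With 1 control array for each change, chosen after seeing the data, r was 0.280 and 0.104 in the 2 possible assignments, with covariances of 0.308 and 0.0911.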

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

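The tests in this part were chosen after the results were seen. Control probe sets, which enter no comparison of genes, carried a signal above that of the wild-type arrays. The spiked hybridization controls had a geometric mean of 50810.2 on the TAK1-deficient arrays, against 4624.69 on the wild-type Igκ+ and 5254.92 on the wild-type Igλ+ arrays. The medians of the unspiked controls averaged 29.3 against 4.70 and 6.15. Among probe sets without a single gene, 29 had a signal of at least 10000 on both TAK1-deficient arrays and under 1000 on all 4 wild-type arrays.

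Most genes differed between the TAK1-deficient and the wild-type Igκ+ arrays. Different signal distributions alone are argued against as the whole cause, since 9159 genes passed after quantile normalization. Weak target that was scaled up to the common mean may be a cause: the spiked controls, added in fixed amounts, were 10.9867 times as bright as on the wild-type Igκ+ arrays. TAK1 deficiency itself cannot be told apart from this, because both TAK1-deficient arrays carry these control signals and no wild-type array does, and Map3k7 stood at percentile 22.8 among genes of similar level, with its other 5 probe sets at 33, 1.4, 14, 12.4 and 16.2.

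The κ transcripts on wild-type Igλ+ replicate 2 had 3 candidate explanations. An array of Igκ+ cells under an Igλ+ name is argued against by its λ signal, a median of 204.12% of the Igκ+ mean. This rests on 3 probe sets of a single gene, Iglv1, which ranged from 103% to 255%. Transcription of κ in Igλ+ cells in general is argued against by replicate 1, with a median of 0.404623%. Igκ+ cells in the sample, which the sort by light chain would remove, remain a possible explanation, since 16 of 16 κ probe sets were at 5% of the Igκ+ mean or more. A difference in κ transcription between the cells of these samples was not tested.

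Granulocyte markers were highest on wild-type Igλ+ replicate 1. A property of Igλ+ cells is argued against by replicate 2, where the median marker stood at -2.39 (log2) relative to the mean of the wild-type arrays. Other bone marrow cells in the sample may be a source: 28 of 31 markers of monocytes, erythroid cells, megakaryocytes and basophils were also highest on this array among the wild-type arrays. These 31 are the listed markers that passed the filter on the mean over all arrays, which a high signal on this array raises. Ppbp, for example, had 1374 here and 2.41 to 24.8 on the other wild-type arrays. For markers so dim elsewhere, being highest here is in part fixed by the filter, so the count overstates the evidence. The depletion of cells bearing CD11b, Gr1 and Ter119 would remove granulocytes, monocytes and erythroid cells. Cells bearing DX5 had been depleted too, and the remaining B cells were sorted by surface light chain. Megakaryocytes and basophils would therefore not be expected either. A difference shared by the arrays without the suffix in their titles stays open as well, with a correlation of 0.222 between the wild-type groups.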

How the results depend on the processing

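Spike-in scaling, the level adjustment and separate control arrays were chosen after seeing the data; the other alternatives were planned. In TAK1-deficient against wild-type Igκ+ cells, the number of genes past the threshold (limma, Benjamini-Hochberg; 8876 as reported) was 14703 without a filter and 19882 with every probe set, where more features are tested, and 4809 with the level adjustment. Without 1 array it ranged from 7897 to 9240. Against wild-type Igλ+ cells (8920) it was 14528, 20004 and 4877, and 7992 to 8690 without 1 array. Between wild-type Igλ+ and Igκ+ cells it was 0 (limma; 239 at unadjusted p under 0.05) under every alternative that keeps both Igλ+ arrays, and ranged from 0 to 68 without 1 array, with 7 without Igλ+ replicate 1 and 68 without replicate 2.

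Genes at least 2-fold apart in all array pairs numbered 6444 for TAK1-deficient against wild-type Igκ+ cells. They were 11585 without a filter, 9827 with median centring, 15271 with every probe set, 9873 with spike-in scaling and 2528 with the level adjustment, and 6444 to 7285 without 1 array. Against Igλ+ cells (6200) the counts were 11105, 9512, 14731, 9674 and 2391, and 6200 to 7309. Between the wild-type groups (19) they were 54 with a pseudocount of 1, 12 with a filter at the 60th percentile, 35 with every probe set, and 19 to 444 without 1 array (213 and 62 without Igκ+ replicates 1 and 2, 132 and 444 without Igλ+ replicates 1 and 2). Without an array of a compared group fewer pairs have to agree, so these counts can only stay or rise.

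Lists past the threshold of limma's camera test numbered 6, 9 and 6 for TAK1-deficient against wild-type Igκ+, wild-type Igλ+ against Igκ+ and TAK1-deficient Igκ+ against wild-type Igλ+ cells. They were 0, 0 and 0 with an estimated correlation, and 2, 3 and 2 with a filter at the 60th percentile, where fewer genes are tested. In the comparisons with TAK1-deficient cells they were 21 and 20 without a filter, 3 and 2 after quantile normalization and 0 and 0 with the level adjustment. Without 1 array they ranged from 5 to 8, 6 to 11 and 6 to 10, with 10 in the last comparison without Igλ+ replicate 1.

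For wild-type Igλ+ against Igκ+ cells 5 list results reversed. Without 1 array the median of the proliferation list ranged from -1.11 to 0.22, of NK cell markers from -2.00 to 0.60, of granulocyte markers from -1.58 to 4.67, of erythroid markers from -0.24 to 1.99 and of megakaryocyte and basophil markers from -1.22 to 3.88. The κ median of TAK1-deficient Igκ+ against Igλ+ cells (2.30) reversed with spike-in scaling (-0.68) and ranged from -0.32 to 4.40 without 1 array; it was 0.07 with median centring and 3.11 with the level adjustment. The λ median (-3.51) was -5.74, -6.50 and -2.35 with median centring, spike-in scaling and the level adjustment. The correlation of both changes against wild-type Igκ+ cells (0.306) was 0.395 and 0.197 with pseudocounts of 1 and 64, 0.125 with the filter at the 60th percentile, 0.0928 after quantile normalization, 0.174 with the level adjustment, 0.280 and 0.104 with separate control arrays, and 0.182 to 0.409 without 1 array. The cause was not tested for results that did not hold.

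The title suffix as a block gave 8914, 0 and 8948 genes (limma, Benjamini-Hochberg) and 5, 11 and 6 lists. The labels give no pairs. Across genes the differences between arrays without and with the suffix correlated at 0.222 between the wild-type groups, and at 0.0124 and 0.0254 between TAK1-deficient and wild-type Igκ+ or Igλ+ arrays. Of the results for single genes, 439, 192 and 437 in the 3 comparisons kept direction and side of the threshold, 1, 0 and 1 lost their call (Map3k7, with the level adjustment) and 4 in the wild-type comparison gained one (Igkv14-111 and Igkv15-103). These counts cover only Map3k7 and the genes named by the rule, each under the alternatives that kept it. The rule took the largest changes or, between the wild-type groups, genes that did not pass, so little movement was to be expected. Over all genes of the first comparison, 3371 of 8876 calls were the same with the level adjustment. The 95th percentile of the unspiked controls, 77.7 and 75.7 on the TAK1-deficient arrays, limits what dim genes can show.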

Other observations

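Igha, Jchain and Gzma, chosen after their values were seen, varied between wild-type arrays of the same group. Igha, which encodes the IgA constant region, had signals of 10263 and 7531 on the wild-type Igκ+ arrays, 8055 and 348 on the Igλ+ arrays, and 205 and 262 on the TAK1-deficient arrays, and Jchain had 9837, 4130, 4147, 117, 526 and 538 on the same arrays. Gzma, a granzyme gene of cytotoxic cells, had 22.6 and 1457 on the wild-type Igκ+ arrays and 387 and 4.12 on the Igλ+ arrays.

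Further gene lists did not pass limma's camera test with Benjamini-Hochberg adjustment in TAK1-deficient against wild-type Igκ+ cells. Of pro-B and pre-B cell genes 6 of 17 rose and 3 fell (adjusted p = 0.0914; 7 passed adjusted over the list alone), with Arpp21 at 1732 against 15.4, Rag2 at 414 against 15.2 and Rag1 at 353 against 124. Of these Rag2 was at the level of unspiked controls on wild-type Igκ+ replicate 2. Dim on all wild-type arrays, Rag2 passed the filter only through the TAK1-deficient arrays. With the level adjustment their log2 changes were 2.88, 1.13 and 0.93, and Rag1 lost its call (limma, Benjamini-Hochberg adjusted p = 0.139). Of MHC class II genes 11 of 13 fell and 2 rose (0.115; 13 adjusted over the list alone), of chemokine receptors 15 of 19 fell and 3 rose (0.110; 18), of Toll-like receptor genes 14 of 19 fell and 1 rose (0.0914; 16), and of MAPK components 11 of 16 fell and 1 rose (0.0914; 14). With the level adjustment 8 pro-B and pre-B cell genes rose and 1 fell, and in the other 4 lists 5, 7, 6 and 6 fell and 4, 1, 3 and 3 rose. The unfolded protein response (0.0606), anergy (0.115), survival (0.144), interferon-stimulated (0.195), BAFF and TNF receptor (0.302), glycolysis (0.355), heat shock (0.442), V(D)J recombination (0.480), p53 (0.610), AP-1 (0.637), plasma cell (0.658), marginal zone and B-1 (0.693), cholesterol (0.707), germinal centre (0.733) and proliferation (0.921) lists followed. In 3 of these, marginal zone and B-1, germinal centre and proliferation, the test pointed up while the median was negative. Markers of dendritic cells (0.114), monocytes (0.170), granulocytes (0.199), megakaryocytes and basophils (0.199), erythroid cells (0.297) and NK cells (0.353) did not pass either. Between wild-type Igλ+ and Igκ+ cells the lists that did not pass ran from monocyte markers (median log2 difference 0.63, adjusted p = 0.0561) to NF-κB components (0.997), and between TAK1-deficient Igκ+ and wild-type Igλ+ cells from T cell markers (median 3.14, adjusted p = 0.0522) to plasma cell genes (0.995).

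The TAK1 kinase complex had 4 measured genes, too few for the list test. In TAK1-deficient Igκ+ cells Tab2 and Tab3, which encode adaptors of TAK1, fell by 0.53 and 1.48 on the log2 scale, and Tab1 rose by 1.10 (limma, Benjamini-Hochberg); all 4 passed adjusted over the list alone. With the level adjustment Tab2 turned to 0.72 (limma, Benjamini-Hochberg adjusted p = 0.00332), and Tab3 (-0.19) and Tab1 (-0.03) lost their calls.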
